A study of Mus musculus with 13 samples.

How the data were processed

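The data are expression values of 13 arrays of the Mouse Gene 2.0 ST type, hybridised with RNA from sorted splenic CD205+CD8+ dendritic cells. Per the labels, 400 ng of RNA was pre-amplified and labelled with biotin, and samples were used where the RNA quality sufficed. The deposited values are log2 probe set values that the authors made with RMA in Affymetrix Expression Console, as named in the submitters' processing notes. Versions are not given in the sources used here. RMA corrects the background, makes the distributions of the arrays alike by quantile normalisation and summarises the probes of a set. A change shared by most genes of an array would thus be removed. Array medians lay between 5.00 and 5.13, no pair of arrays was identical, and the Pearson correlation between arrays across probe sets was 0.988 to 0.996. Scanner files and detection calls were not used here. The genome build behind the probe sets is not given in the sources used here, and no coordinates are printed.

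Of 41345 probe sets, 23521 were listed with 1 gene symbol, 1814 with several and 16010 were not listed. The first of these were reduced to 22180 genes, and for the 1082 genes with more than 1 probe set the probe set with the highest mean over all arrays was used. Gene IDs of 21994 genes were found in the RefSeq gene table, which changed 0 symbols, and the other 186 genes kept the symbol of the probe table. The 17824 remaining probe sets were tested apart, and 1 was lower in CD103 high cells of PBS mice and 1 in the average over treatments. No gene was left out for a low value. As a measure of background, chosen after the values were seen, genes were compared with the 95th percentile of 1105 olfactory receptor genes.

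All 13 arrays were fitted in limma 3.58.1 (R 4.3.3) with lmFit, 1 mean per group, contrasts.fit and eBayes, so that the groups share an estimate of the spread, with 9 residual and 3.86 prior degrees of freedom. The 7 contrasts were CD103 high against low within each treatment, MDP against PBS within each subset, the average of each pair, and their interaction. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes of a contrast, and the threshold was an adjusted p of 0.05. Values are given as log2 differences ± SE from the fit, or as group means ± SD with n. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9. The number of arrays, 3 or 4 per group, limits the precision, with a median SE of 0.0754 to 0.151 over the contrasts.

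Gene lists were fixed before the data were examined, as were the groups, contrasts, tests, rules for naming genes and most of the alternatives. The 16 gene lists were cDC1 identity, CCR7-type mature dendritic cell, tolerance-associated, GM-CSF receptor and STAT5 response, NOD2 pathway, NF-kB targets, interferon-stimulated, antigen presentation, pattern-recognition receptors, migration and adhesion, cell cycle, cholesterol synthesis, glycolysis, oxidative phosphorylation, immediate-early and dissociation stress, and apoptosis and p53 response. The 9 marker lists were plasmacytoid dendritic cell, cDC2, monocyte and macrophage, neutrophil and granulocyte precursor, B cell, T cell, natural killer cell, erythroid cell and B16 melanoma. Members without a probe set of their own, such as Clec9a, Ripk2, Nfkb1 and Cd74, were not analysed here; they include 6 of 12 erythroid markers. Each list was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg over the gene lists, and over the marker lists, of a contrast. Beside it stand camera with a correlation estimated from the residuals, fry, and the number of members past the threshold over all genes and adjusted over the list alone. Of 112 tests of a gene list, 49 passed with the preset correlation and 0 of these with an estimated correlation, and 6 passed with fry.

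Genes were named by rule. For each contrast these are the 10 largest rises and the 10 largest falls past the threshold whose groups of arrays did not overlap. Averages instead needed the same sign in both parts, and the interaction only the threshold. Where no gene qualified, the 5 with the smallest p were named. From the lists discussed, up to 2 members that rose and 2 that fell with the smallest p were named, or the 2 with the smallest p where no member passed. Always named were Itgae, Cd8a, Ly75, Nod2, Csf2ra, Csf2rb and Csf2rb2. Predicted genes, microRNAs, small nucleolar RNAs, antigen receptor segments and the olfactory and vomeronasal receptor families were counted but not named under the size rule. Scarna10, a small Cajal body RNA, was not covered by this and is named. Xist, the Y-linked genes, Kdm6a and Kdm5c were named after their values were seen.

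The replicate numbers of the labels recur across groups without a stated meaning. To see whether they pair samples, each array's deviations from its group mean were correlated over genes above the median expression. Xist, Eif2s3y, Kdm5d and Uty were left out, while Kdm6a, Kdm5c and the other genes of the sex chromosomes stayed in. Arrays of the same treatment and number (MDP 2 and 3, PBS 4 and 6) had r of 0.254, 0.115, 0.225 and 0.289, so that all 4 pairs exceeded 0.1, and 8 of 8 such arrays correlated best with their own number. The 17 pairs of the same treatment and other numbers had r of -0.254 to 0.18. The 3 pairs of the same subset and number across treatments had -0.13 to 0.0575. The 4 pairs also shared their Xist state. The pairing is thus read from the data, and a fit with treatment and number as a block (duplicateCorrelation, consensus correlation 0.183) is given beside the results it changes.

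Each result was recomputed with the lowest 25% or 50% of genes left out, the mean of a gene's probe sets, renewed quantile normalisation and centring by the array median. Further alternatives were a variance trend with robust eBayes, array weights, only the arrays of the groups compared, the replicate block (also by number alone, and as a fixed block on the 4 pairs), a 2-fold minimum, and each array left out in turn. Calls of named genes are counted as lost or kept over all alternatives, apart from the 2-fold minimum. Xist state as a covariate, alone and with the block, and list tests with the block were added after seeing the data. Arrays of the groups compared were also regrouped, in all possible splits or 100 drawn with a fixed seed. Splits that treat the same-numbered arrays of a treatment as pairs were added after seeing the data. Between subsets these part as many pairs as the real split, and between treatments they keep each pair in 1 treatment.

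The fit was tested on simulated data with the spread of these arrays, in which 200 of 22180 genes changed by a log2 change of 0.5, 1 or 2. For MDP against PBS in CD103 high cells, 48.5%, 91% and 98.5% of these were recovered, with 3 unchanged genes called. In CD103 low cells 58%, 92.1% and 98.2% were recovered with 12 unchanged genes called, and between the subsets 53.6%, 97% and 98.5% in PBS mice with 8, and 57.1%, 93.9% and 100% in MDP mice with 23. For the interaction, 12.1%, 73.8% and 100% were recovered with 4 unchanged genes called. For the average over treatments the shares were 85.5%, 100% and 100% with 10, and for the average over subsets 73.1%, 100% and 100% with 15. No changed gene was called in the wrong direction (0 in each contrast). In the simulation of MDP against PBS in CD103 high cells, 1 shifted list of 30 genes among 25 had an adjusted p = 4.29e-59 with the preset and an adjusted p = 4.13e-07 with an estimated correlation, and 0 others were called. The simulated genes and arrays varied independently of each other. Genes of a list that vary together were not simulated, so the rate of false list calls in these data is not estimated.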

Results

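Gene expression was measured in CD205+CD8+ dendritic cells sorted from the spleens of C57Bl/6 littermate mice labelled male. CD8+ dendritic cells of this kind, known as type 1 conventional dendritic cells (cDC1), take up dead cells and present their antigens to CD8 T cells. At 6 weeks of age the mice received a subcutaneous B16 melanoma that secretes Flt3L, a growth factor that expands dendritic cells. After 5 days they were injected with 100 ul of PBS, with or without 50 ug of muramyl dipeptide (MDP), a fragment of bacterial peptidoglycan sensed by the receptor NOD2. Spleens were taken after 24 h and the cells were sorted again by surface CD103, the αE integrin encoded by Itgae, which binds E-cadherin. RNA was measured on 13 arrays, which fall into PBS CD103 low (n = 4), PBS CD103 high (n = 3), MDP CD103 low (n = 3) and MDP CD103 high (n = 3). The number of arrays per group limits the precision of every value. Nothing states that each array came from its own mouse, so p-values measure only the spread between these samples.

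Across the 13 arrays, transcripts of the other sorted surface proteins were abundant, with a mean log2 value of 10.37 for Cd8a and 9.30 for Ly75, which encodes CD205. Nod2 had a mean of 6.70. The median over all genes was 5.27, and the 1105 olfactory receptor genes, used as a measure of background, had a median of 2.97 and a 95th percentile of 5.12. Arrays differed in the transcripts of the sex chromosomes. Xist, the RNA that silences an X chromosome in female cells, lay between 10.98 and 11.21 in 7 arrays and between 4.47 and 6.69 in the other 6. The mean of the Y-linked genes Eif2s3y, Kdm5d and Uty was 3.50 to 4.39 in the former and 7.85 to 8.21 in the latter. MDP CD103 low replicate 1 also stood apart, with a mean of 8.50 over 28 genes of mature, CCR7-positive dendritic cells against 7.45 and 7.47 in the other arrays of its group.

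The difference between the CD103 subsets without MDP shows what else parts cells sorted on this integrin. In PBS mice, Itgae (probe set 17252574, Entrez gene 16407) was 4.69-fold higher in CD103 high than in CD103 low cells, at 10.15 ± 0.08 (SD, n = 3) against 7.92 ± 0.41 (SD, n = 4) on the log2 scale (adjusted p = 0.00376). Emb (probe set 17290083, Entrez gene 13723), which encodes embigin, a chaperone of lactate transporters, was lower by a log2 difference of -1.51 ± 0.15 (SE, adjusted p = 0.00376). CD103 high cells also had less Cdk6, a kinase of the G1 phase, at -0.87 ± 0.13 (adjusted p = 0.0328), and less Bcl2, which protects cells from apoptosis, at -0.57 ± 0.09 (adjusted p = 0.0413). They had more Plpp3, a phosphatase of signalling lipids, at 1.04 ± 0.16 (adjusted p = 0.0403).

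In all, 17 of 22180 genes passed the threshold between the subsets of PBS mice, 10 higher and 7 lower in CD103 high cells. The other named genes that were higher were Gpr82, an orphan receptor (0.92 ± 0.14), Pacsin1 (0.90 ± 0.13), Cd300c (0.90 ± 0.13), Fcrla (0.75 ± 0.09), the phospholipase Plb1 (0.74 ± 0.11) and Ttc39b (0.47 ± 0.08), with adjusted p from 0.0121 for Fcrla to 0.0433 for Ttc39b. Chst9, a sulfotransferase (0.96 ± 0.13, adjusted p = 0.0285), and the lactate receptor Hcar1 (0.70 ± 0.11, adjusted p = 0.0353) had mean values inside the olfactory receptor range. Cdca7, a gene transcribed as cells enter S phase (-0.70 ± 0.11, adjusted p = 0.0433), the nucleic acid binding protein Ybx3 (-0.54 ± 0.08, adjusted p = 0.0294) and vinculin, Vcl (-0.42 ± 0.07, adjusted p = 0.0413), were lower. For each named gene the arrays of the groups did not overlap, as the rule for naming required. Of the 16 named genes, only the call of Itgae was kept in every alternative, and that of Vcl was lost in 17 of 25. With the mean of its probe sets, Emb differed by -0.74 and Bcl2 by -0.35, both past the threshold. The count of 17 was 5, 2, 6 and 2 without PBS CD103 low replicates 1, 3, 4 and 6, and 9, 2 and 5 without PBS CD103 high replicates 4, 5 and 6. It was 7, 3 and 4 without MDP CD103 high replicates 2, 3 and 4, and 1 when only the arrays of these groups were fitted.

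Of 13 measured markers of plasmacytoid dendritic cells, Pacsin1 and Cd300c were higher in CD103 high cells of PBS mice, also when adjusted over the list alone, while the list as a set did not pass (median 0.09, adjusted p = 0.628). Fcrla was the 1 of 11 B cell markers that was higher (adjusted p = 0.971 for the list). None of the 31 measured cell cycle genes passed, over all genes or adjusted over the list alone, yet 29 lay below 0 and the list was lower as a set, with a median of -0.15 (adjusted p = 2.25e-05, but adjusted p = 0.647 with an estimated correlation). Mcm2 (-0.43, adjusted p = 0.365) and Mcm6 (-0.39, adjusted p = 0.389), parts of the replicative helicase, had the smallest p in it. The list of CCR7-type mature dendritic cell genes had a median of 0.19, with 25 of 28 above 0 (adjusted p = 0.00189, but adjusted p = 0.647 with an estimated correlation). The lists of cDC1 identity (median 0.04, adjusted p = 0.0157), NF-kB targets (0.15, adjusted p = 0.021), oxidative phosphorylation (-0.05, adjusted p = 0.021) and cholesterol synthesis (-0.08, adjusted p = 0.0265) passed with the preset correlation and had an adjusted p = 0.647 with an estimated correlation. The size of these medians depended on single arrays. That of the cell cycle list was -0.26 without PBS CD103 high replicate 4 and -0.07 without replicate 6, and that of oxidative phosphorylation -0.08 and -0.03. Without PBS CD103 high replicate 5 it was 0.07 for the mature list, 0.07 for the NF-kB targets and 0.06 for cDC1 identity, and without PBS CD103 low replicate 6 it was 0.12 for the mature list. The plasmacytoid median reached -0.03 with 1 array left out.

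The same contrast in MDP mice asks whether the subsets differ after NOD2 stimulation. Esco2, which acetylates cohesin in S phase, was higher in CD103 high cells by a log2 difference of 1.33 ± 0.14 (SE, n = 3 against 3, adjusted p = 0.00698). Mastl, a kinase needed to hold cells in mitosis, was higher by 1.18 ± 0.18 (adjusted p = 0.018), and Rrm2, a subunit of the enzyme that makes deoxynucleotides, by 1.07 ± 0.15 (adjusted p = 0.018). The chemokine Ccl5 differed by -2.88 ± 0.47 (adjusted p = 0.0221) and Ccr7, the receptor that guides dendritic cells to T cell zones, by -1.76 ± 0.34 (adjusted p = 0.0437). These SEs pool the spread of all groups, while MDP CD103 low cells had an SD of 1.17 for Ccl5 and 0.97 for Ccr7. For Ccr7 the SD was 0.06 in PBS CD103 low cells. Ccr7 was 10.37 in MDP CD103 low replicate 1 against 8.58 and 8.84 in the other arrays of its group.

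Between the subsets of MDP mice, 116 genes passed, 105 higher and 11 lower in CD103 high cells. The centromere gene Cenpi (1.12 ± 0.18), the centriole gene Stil (1.10 ± 0.18), the DNA polymerase Polq (1.06 ± 0.18), Lrr1 (1.01 ± 0.16), the E2F family repressor E2f7 (1.00 ± 0.13), the kinetochore gene Kntc1 (0.99 ± 0.13) and the chromosome motor Kif4 (0.99 ± 0.14) were higher, with adjusted p from 0.0152 to 0.0247. The tetraspanin Cd63 (-2.36 ± 0.46, adjusted p = 0.0439), the interferon-inducible Gbp10 (-1.29 ± 0.23, adjusted p = 0.031), the prostaglandin E2 receptor Ptger4 (-0.68 ± 0.12, adjusted p = 0.0247) and Vegfa (-0.46 ± 0.08, adjusted p = 0.0258) were lower. So were Zmynd15, Dusp5 and Zfas1, with adjusted p from 0.0247 to 0.0463. Itgae itself was higher by 1.22 ± 0.25, at 11.35 ± 0.22 against 10.13 ± 0.52 (SD), which narrowly missed the threshold (adjusted p = 0.0529) and passed it with same-numbered arrays as a replicate block (adjusted p = 0.0242). None of the 21 named genes past the threshold kept its call in every alternative, and Cd63, Ccr7 and Dusp5 lost theirs in 15 of 25. With the replicate block the count of genes was 190. It was 0 without MDP CD103 high replicate 2 or 3, 64 without replicate 4, and 16 and 66 without MDP CD103 low replicates 1 and 3. It was 76 and 77 without PBS CD103 low replicates 1 and 4, and 0 when only the arrays of these groups were fitted.

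Of the 31 cell cycle genes, 6 were higher in CD103 high cells of MDP mice and 28 were when adjusted over the list alone. All 31 lay above 0, and the median was 0.66. The list passed as a set (adjusted p = 1.06e-34, but adjusted p = 0.195 with an estimated correlation). Rrm2 and thymidine kinase, Tk1 (0.49 ± 0.08, adjusted p = 0.018), had the smallest p. All 28 CCR7-type mature genes lay below 0, with a median of -0.57. Of these, 2 (Ccl5 and Ccr7) were lower, and 16 were when adjusted over the list alone (adjusted p = 2.47e-18 for the list, but adjusted p = 0.218 with an estimated correlation). No NF-kB target passed over all genes and 6 were lower when adjusted over the list alone. Ptgs2, the inducible cyclooxygenase, was nearest (-1.25, adjusted p = 0.0529), with adjusted p = 9.52e-10 for the list, but adjusted p = 0.218 with an estimated correlation. Sirpa, the receptor that marks type 2 conventional dendritic cells (cDC2), was the 1 of 13 cDC2 markers that was lower (-0.50 ± 0.09, adjusted p = 0.0308). That list had a median of -0.12 (adjusted p = 0.0488, but adjusted p = 0.294 with an estimated correlation). Of 20 immediate-early and dissociation stress genes, 18 lay below 0, with a median of -0.15 (adjusted p = 0.0106, but adjusted p = 0.481 with an estimated correlation) that was -0.02 without MDP CD103 high replicate 4. Interferon-stimulated genes had a median of -0.18 (adjusted p = 0.0106, but adjusted p = 0.481 with an estimated correlation), from -0.29 to -0.08 over all arrays left out. The GM-CSF list had -0.18 (adjusted p = 0.000653, but adjusted p = 0.299 with an estimated correlation), and -0.10 without MDP CD103 low replicate 1. Cholesterol synthesis genes had -0.16 (adjusted p = 0.000174, but adjusted p = 0.308 with an estimated correlation), from -0.25 to -0.08. Migration and adhesion genes had -0.07 (adjusted p = 0.0312, but adjusted p = 0.218 with an estimated correlation), from -0.10 to -0.03, and glycolysis genes 0.06 (adjusted p = 0.026, but adjusted p = 0.375 with an estimated correlation), from 0.004 to 0.11. Both the cell cycle and the mature list followed MDP CD103 low replicate 1, whose cell cycle mean was 8.08 against 8.52 and 8.55 in the other arrays of its group. Without it the median was -0.25 for the mature list and -0.19 for the NF-kB targets, against -0.32 with all arrays. Mature genes past the threshold numbered 4 without MDP CD103 low replicate 2 and 0 without MDP CD103 high replicate 2 or 3. They numbered 1 without MDP CD103 low replicate 3, MDP CD103 high replicate 4 or any 1 of the 7 PBS arrays. The call of Sirpa was lost without MDP CD103 low replicate 1 or 3, PBS CD103 low replicate 1 or any 1 of the 3 MDP CD103 high replicates. The number of cell cycle genes past the threshold was 1, 4 and 3 without MDP CD103 low replicates 1, 2 and 3, and 3, 3 and 2 without PBS CD103 low replicates 1, 3 and 4. It was 2 without PBS CD103 high replicate 5, 2 without MDP CD103 high replicate 4, and 0 without MDP CD103 high replicate 2 or 3.

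MDP against PBS within the CD103 low cells compares the cells found in that sort gate 24 h after injection. Cells were sorted on CD103 after MDP, so a gate need not hold the same cells in both treatments. The response of a subset, here and below, means this difference between treatments within a gate. Itgae rose 4.62-fold, from 7.92 ± 0.41 (SD, n = 4) to 10.13 ± 0.52 (SD, n = 3) on the log2 scale (adjusted p = 0.00838), beside a mean of 10.15 ± 0.08 in the CD103 high cells of PBS mice. The MDP arrays lay between 9.64 and 10.68 and the PBS arrays between 7.46 and 8.35, as the plot of single genes per array shows. It was the 1 gene past the threshold in limma, while 1343 genes had an unadjusted p under 0.05. With same-numbered arrays as a block the count was 2. The adjusted p of Itgae was 0.0787 without MDP CD103 low replicate 2, 0.0566 without PBS CD103 low replicate 4, 0.0569 with a variance trend and robust fit, and 0.331 when only the arrays of these groups were fitted, which brought the count to 0 in each case. The count was 2 without PBS CD103 low replicate 3 or PBS CD103 high replicate 6.

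**Figure D1:**
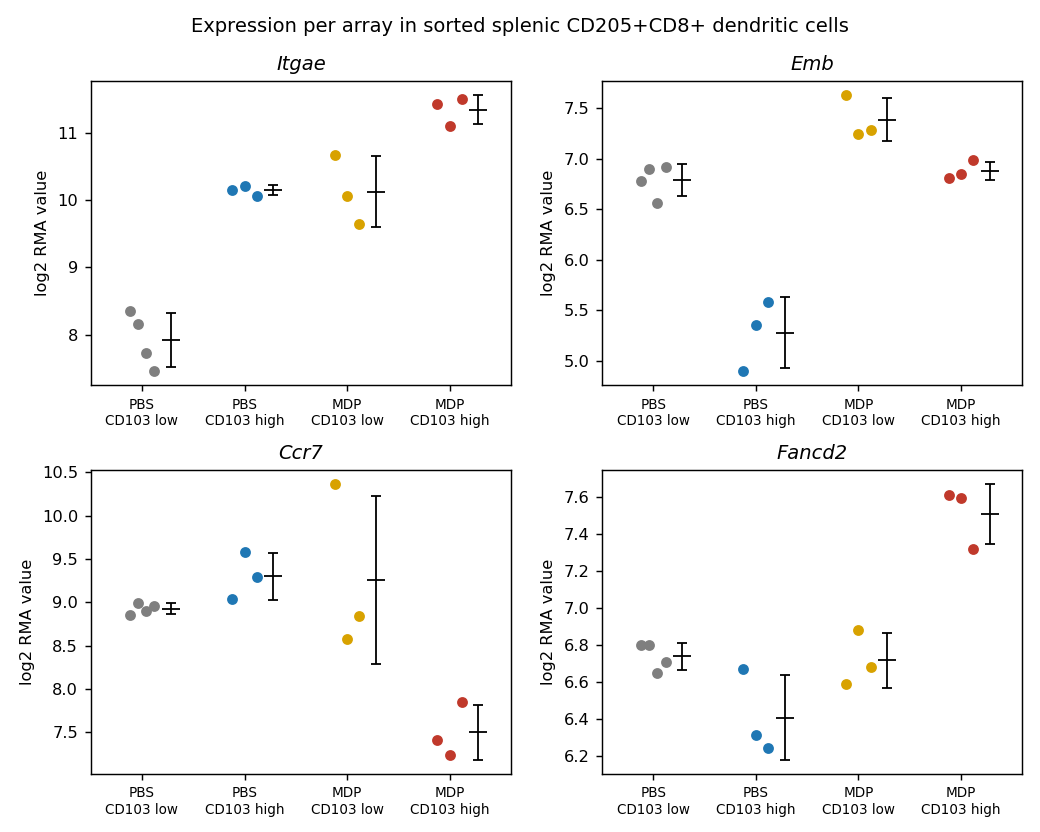
Log2 RMA values of Itgae, Emb, Ccr7 and Fancd2 in each array, by group (points, arrays; bars, mean ± SD). Itgae in the MDP CD103 low arrays, 9.64 to 10.68, lies above all PBS CD103 low arrays, 7.46 to 8.35.

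No member of the 25 gene and marker lists passed in the CD103 low cells, over all genes or adjusted over the list alone. As sets, CCR7-type mature genes (median 0.24, adjusted p = 0.000114), immediate-early and dissociation stress genes (0.17, adjusted p = 0.000552), NF-kB targets (0.15, adjusted p = 0.00617), GM-CSF receptor and STAT5 response genes (0.10, adjusted p = 0.00728), oxidative phosphorylation genes (0.05, adjusted p = 0.0211) and apoptosis and p53 response genes (0.07, adjusted p = 0.0241) were higher with the preset correlation, and each had an adjusted p = 0.717 with an estimated correlation. The cell cycle list was lower, with a median of -0.13 (adjusted p = 0.0127, but adjusted p = 0.873 with an estimated correlation). Without MDP CD103 low replicate 1, the median turned to -0.06 for the mature list, -0.05 for the NF-kB targets and 0.06 for the cell cycle list. Without any 1 array, it reached 0.39 for the mature list at most and -0.20 for the cell cycle list at least. Over all arrays left out it ranged from 0.02 to 0.12 for the GM-CSF list, from 0.10 to 0.26 for the immediate-early list and from 0.03 to 0.09 for the apoptosis list. Among members with the smallest p were Il15ra (0.49, adjusted p = 0.793) and Ccl17 (0.24, adjusted p = 0.803) of the mature list, Ptgs2 (0.85, adjusted p = 0.741) of the NF-kB targets, Egr3 (0.61, adjusted p = 0.741) of the immediate-early genes, and Csf2rb2 (0.31, adjusted p = 0.741) of the GM-CSF list.

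MDP against PBS within the CD103 high cells makes the same comparison in the other gate. Emb rose by a log2 change of 1.60 ± 0.16 (SE, n = 3 against 3, adjusted p = 0.00428), from 5.28 to 6.88, beside a mean of 6.79 in PBS CD103 low cells. Cdc6, which loads the replicative helicase (1.27 ± 0.16, adjusted p = 0.00428), and Lrr1, which helps remove it (1.35 ± 0.16, adjusted p = 0.00428), rose as well. Ccl5 (-2.23 ± 0.47, adjusted p = 0.0311), Ccr7 (-1.80 ± 0.34, adjusted p = 0.0194) and the NF-kB subunit Relb (-1.07 ± 0.24, adjusted p = 0.0413) fell. Itgae rose 2.29-fold, from 10.15 ± 0.08 to 11.35 ± 0.22 (SD, adjusted p = 0.029).

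Altogether 403 genes passed in CD103 high cells, 315 higher and 88 lower after MDP, and 32 of these changed at least 2-fold. The kinetochore genes Ska3 (1.14 ± 0.16, adjusted p = 0.0052) and Ndc80 (1.11 ± 0.15, adjusted p = 0.00491), the repair helicase Brip1 (1.23 ± 0.21, adjusted p = 0.012), the chromatin factor Atad2 (1.12 ± 0.16, adjusted p = 0.0052) and Mtss1, a regulator of actin and membrane shape (1.38 ± 0.30, adjusted p = 0.0338), rose. Scarna10, a small Cajal body RNA, rose by 1.41 ± 0.26 (adjusted p = 0.0154) from a mean inside the olfactory receptor range. Lrrc32, which encodes GARP, the cell surface anchor of latent TGF-beta, fell by 1.13 ± 0.15 (adjusted p = 0.00495), and Ltbp2, a protein of the extracellular matrix, fell by 0.98 ± 0.23 (adjusted p = 0.0459). The stress gene Gadd45b (-1.99 ± 0.41, adjusted p = 0.0271), the IgG receptor Fcgr4 (-1.16 ± 0.24, adjusted p = 0.0288), Gbp10 (-1.13 ± 0.23, adjusted p = 0.029), the adhesion receptor Adgrf5 (-1.66 ± 0.34, adjusted p = 0.026) and Mab21l3 (-2.00 ± 0.35, adjusted p = 0.0134) fell as well. The count of 403 was 109 and 124 without MDP CD103 high replicates 2 and 3, 94 and 82 without PBS CD103 high replicates 5 and 6, and 200 when only these arrays were fitted. Of 31 named genes, 9 kept their call in every alternative: Emb, Lrr1, Cdc6, Ska3, Atad2, Ndc80, Lrrc32, Cd300c and Fcrla. The call was lost in 12 of 25 for Relb (adjusted p up to 0.165), 10 for Ltbp2 (up to 0.199), 9 for Mtss1 (up to 0.126) and 9 for Tnfaip3 (up to 0.145). The call of Itgae was lost without any 1 of the 6 CD103 high arrays, with adjusted p of 0.115, 0.061 and 0.0884 without MDP CD103 high replicates 2, 3 and 4, and 0.0654, 0.0948 and 0.124 without PBS CD103 high replicates 4, 5 and 6. With the mean of its probe sets, Emb rose by 0.79.

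As a set, the cell cycle list was higher in CD103 high cells after MDP in camera (adjusted p = 2.78e-34, but adjusted p = 0.202 with an estimated correlation, and adjusted p = 0.0121 in fry). All 31 measured genes lay above 0, 20 rose over all genes and 29 when adjusted over the list alone. The median change was 0.72 with a mean of 0.67 (95% interval 0.34 to 1.00). Rrm1, the large subunit of ribonucleotide reductase (1.01 ± 0.16, adjusted p = 0.00842), and Mcm3, part of the replicative helicase (0.75 ± 0.12, adjusted p = 0.00893), had the smallest p. The per-array mean of the list was 8.85 to 9.06 in MDP CD103 high cells and 8.13 to 8.53 in PBS CD103 high cells. The number of members past the threshold was 3 without MDP CD103 high replicate 2 or 3, 1 without PBS CD103 high replicate 5 and 0 without PBS CD103 high replicate 6, with medians from 0.64 to 0.81 over all arrays left out.

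**Figure D2:**
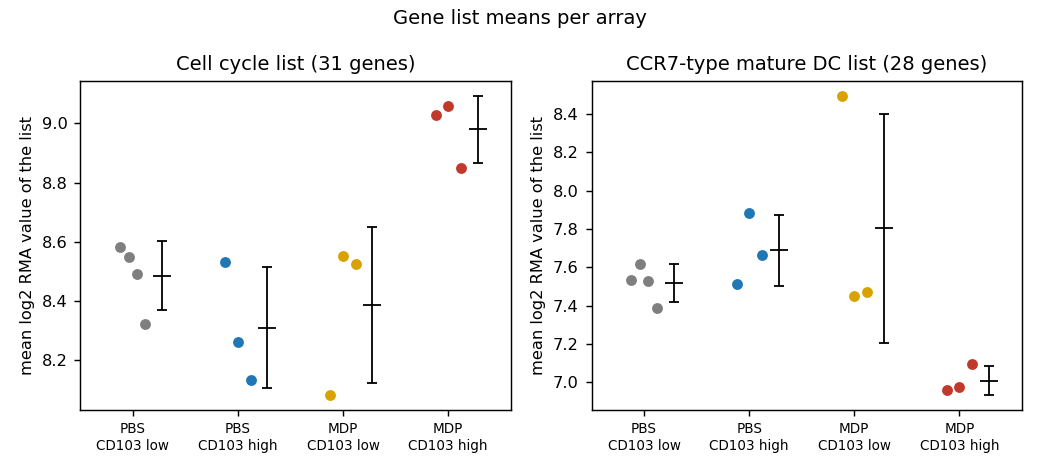
Mean log2 RMA value per array of the 31 cell cycle genes and of the 28 CCR7-type mature dendritic cell genes, by group (points, arrays; bars, mean ± SD). The MDP CD103 high arrays have cell cycle means of 8.85 to 9.06 and mature means of 6.96 to 7.09, and MDP CD103 low replicate 1 has 8.08 and 8.50.

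Of 28 CCR7-type mature genes, 5 fell in the same cells and 15 did when adjusted over the list alone, with a median of -0.55 (adjusted p = 4.51e-14, but adjusted p = 0.279 with an estimated correlation). Ccr7 and Birc3, an inhibitor of apoptosis (-0.49 ± 0.09, adjusted p = 0.0192), had the smallest p. Of 24 NF-kB targets, 5 fell, with Birc3 and Tnip1, an inhibitor of NF-kB signalling (-0.57 ± 0.12, adjusted p = 0.026), foremost. Adjusted over the list alone, 10 fell and 1 rose, and the median was -0.32 (adjusted p = 1.56e-06, but adjusted p = 0.292 with an estimated correlation). In the NOD2 pathway list, 2 of 20 genes fell, Birc3 and the deubiquitinase Tnfaip3 (-0.63 ± 0.13, adjusted p = 0.0338), also when adjusted over the list alone (median -0.08, adjusted p = 0.0191, but adjusted p = 0.303 with an estimated correlation). Both also stand among the NF-kB targets. Interferon-stimulated genes had a median of -0.28 with no member past the threshold and 3 of 27 lower when adjusted over the list alone (adjusted p = 4.24e-05, but adjusted p = 0.462 with an estimated correlation). The median lay from -0.40 to -0.19 over all arrays left out. Ifit1 (-0.35, adjusted p = 0.0729) and Oasl2 (-0.91, adjusted p = 0.121) had the smallest p. Without MDP CD103 low replicate 1, which had the highest mean of the mature list, 15 mature genes and 8 NF-kB targets fell. Mature genes past the threshold numbered 0 without MDP CD103 high replicate 2 or 3 or PBS CD103 high replicate 5 or 6, and 3 without MDP CD103 high replicate 4, PBS CD103 high replicate 4, or any 1 of PBS CD103 low replicates 1, 3, 4 and 6. NF-kB targets numbered 1 without MDP CD103 high replicate 2 or 4, 0 without MDP CD103 high replicate 3 or PBS CD103 high replicate 5 or 6, 2 without PBS CD103 low replicate 1 or 3, and 3 without PBS CD103 low replicate 4 or 6. NOD2 pathway genes numbered 0 without MDP CD103 high replicate 2 or 3 or PBS CD103 high replicate 5 or 6, and 1 without MDP CD103 high replicate 4 or PBS CD103 low replicate 1 or 3.

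Of 13 glycolysis genes, 2 rose in CD103 high cells after MDP and 4 did when adjusted over the list alone, with a median of 0.18 (adjusted p = 4.24e-05, but adjusted p = 0.227 with an estimated correlation, and adjusted p = 0.0121 in fry). They were pyruvate kinase, Pkm (0.35 ± 0.06, adjusted p = 0.0128), and triosephosphate isomerase, Tpi1 (0.39 ± 0.08, adjusted p = 0.0218). The number was 0 without MDP CD103 high replicate 2 or PBS CD103 high replicate 5 or 6, and 1 without MDP CD103 high replicate 3 or 4, and the median was 0.10 without PBS CD103 high replicate 6. Oxidative phosphorylation genes had a median of 0.05 with no member past the threshold (adjusted p = 0.017, but adjusted p = 0.477 with an estimated correlation), which was 0.09 without PBS CD103 high replicate 4 and 0.02 without replicate 6. Pattern-recognition receptors had a median of -0.10 and no member past the threshold (adjusted p = 0.0656, adjusted p = 0.0479 with the replicate block, adjusted p = 0.227 with an estimated correlation, and adjusted p = 0.0235 in fry with the replicate block), with medians from -0.11 to -0.05 over all arrays left out. Ccr7 was the 1 of 23 migration and adhesion genes that fell (list median -0.05, adjusted p = 0.166). Msmo1, a sterol oxidase, was the 1 of 14 cholesterol synthesis genes that did (-0.45 ± 0.09, adjusted p = 0.0187), with a list median of -0.02 (adjusted p = 0.317). Gadd45b was the 1 of 13 apoptosis and p53 response genes, a list whose median of 0.01 and mean of -0.19 differ in sign (adjusted p = 0.909). Each of these 3 calls was lost without MDP CD103 high replicate 2 or 3 or PBS CD103 high replicate 5 or 6, and the medians lay from -0.06 to -0.02, from -0.07 to 0.007 and from -0.02 to 0.02 over all arrays left out.

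Other lists did not pass as sets in CD103 high cells after MDP. The median was -0.03 for cDC1 identity (adjusted p = 0.226), with Nfil3, a transcription factor of cDC1 development, nearest to the threshold (-0.49, adjusted p = 0.0507). It was -0.09 for tolerance-associated genes (adjusted p = 0.103), where Pdcd1lg2 (-0.50, adjusted p = 0.115) and Cd274 (-0.95, adjusted p = 0.13), the ligands of PD-1, had the smallest p. It was -0.08 for GM-CSF receptor and STAT5 response genes (adjusted p = 0.0785), -0.04 for antigen presentation (adjusted p = 0.354) and 0.04 for immediate-early and dissociation stress genes (adjusted p = 0.805). Among the markers of other cells, the plasmacytoid genes Cd300c (-0.96 ± 0.14, adjusted p = 0.0052) and Pacsin1 (-0.77 ± 0.14, adjusted p = 0.013) fell, as did the B cell marker Fcrla (-0.72 ± 0.10, adjusted p = 0.00491) and the monocyte marker Fcgr4. The lists' medians were -0.06 for plasmacytoid dendritic cells (adjusted p = 0.691, and adjusted p = 0.026 in fry), -0.05 for B cells (adjusted p = 0.876) and -0.06 for monocytes and macrophages (adjusted p = 0.691). Medians were -0.03 for cDC2 (adjusted p = 0.691), -0.07 for neutrophils and their precursors (adjusted p = 0.876), -0.01 for T cells (adjusted p = 0.956), 0.01 for natural killer cells (adjusted p = 0.911), 0.02 for erythroid cells (adjusted p = 0.991) and -0.04 for B16 melanoma (adjusted p = 0.876). With 1 array left out, the median turned in sign for immediate-early genes (-0.08 to 0.14), plasmacytoid dendritic cells (-0.09 to 0.03), T cells (-0.02 to 0.03), natural killer cells (-0.05 to 0.01), erythroid cells (-0.03 to 0.05) and B16 melanoma (-0.05 to 0.03). It reached -0.16 for the GM-CSF list, -0.06 for the tolerance list, -0.07 for antigen presentation, -0.05 for cDC2, -0.01 for cDC1 identity, -0.02 for neutrophils, -0.02 for monocytes and macrophages and -0.002 for B cells. The fall of Fcgr4 was lost without any 1 of the 3 MDP CD103 high replicates or PBS CD103 high replicate 5 or 6, and that of Pacsin1 without MDP CD103 high replicate 2 or PBS CD103 high replicate 5.

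**Figure D3:**
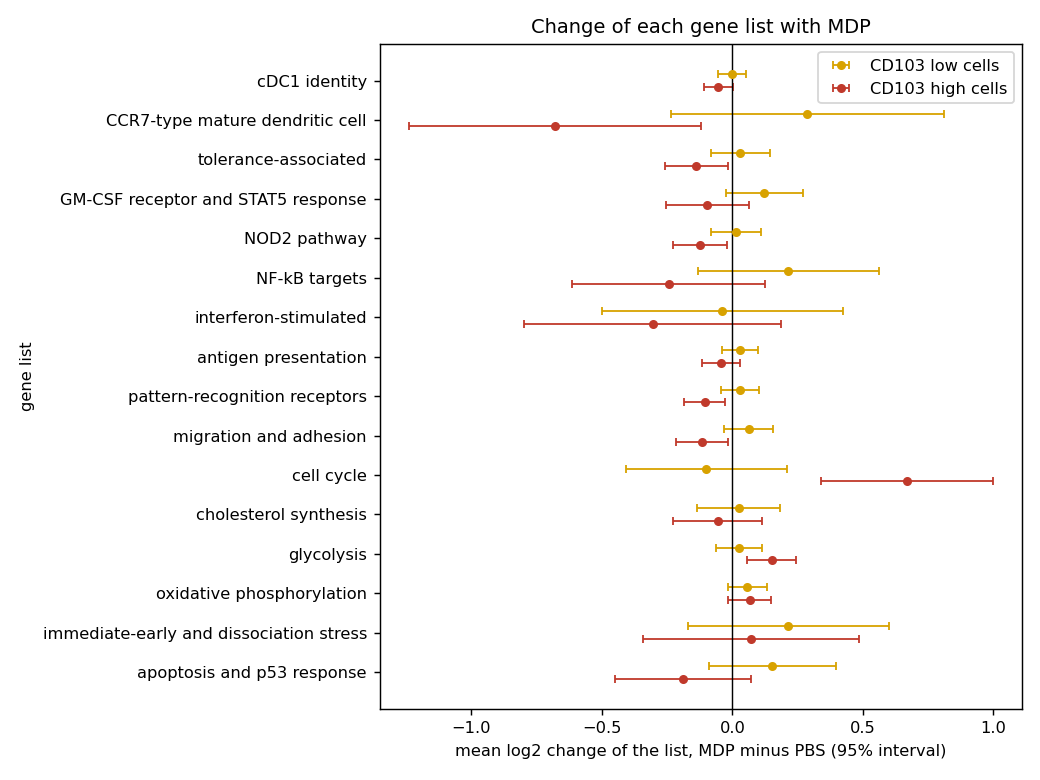
Mean log2 change with MDP of each of 16 gene lists in CD103 low and in CD103 high cells (points, mean over the list; bars, 95% interval). The cell cycle list has 0.67 in CD103 high cells with an interval from 0.34 to 1.00, and the CCR7-type mature list has -0.68 with an interval from -1.24 to -0.12.

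The test of whether the subsets responded differently to MDP found 16 genes in limma, 16 with a higher and 0 with a lower response in CD103 high cells, with 2137 genes at an unadjusted p under 0.05. The response was larger in CD103 high cells for Esco2 by 1.43 ± 0.19, for Ndc80 by 1.39 ± 0.20, for Atad2 by 1.36 ± 0.22, for Kif4 by 1.27 ± 0.19, and for the helicase Blm by 1.21 ± 0.19. It was also larger for the condensin gene Ncapg2 by 1.12 ± 0.18, for the Fanconi anaemia gene Fancd2 by 1.12 ± 0.17, for Rad54l, a gene of homologous recombination, by 1.05 ± 0.17, for Mms22l by 1.04 ± 0.17, and for Cdc7, a kinase that starts replication forks, by 1.03 ± 0.17. Each of them had an adjusted p of 0.0486, and none of these 10 calls was kept in every alternative (adjusted p up to 0.161). The cell cycle list differed as a set, with a median of 0.79 (adjusted p = 5.21e-34, but adjusted p = 0.202 with an estimated correlation). No member passed over all genes, Top2a being nearest at 1.14 (adjusted p = 0.0843), and 29 of 31 did when adjusted over the list alone. The CCR7-type mature list had a median of -0.81 (adjusted p = 1.41e-18, but adjusted p = 0.202 with an estimated correlation), with Ccl5 at -3.11 (adjusted p = 0.088) and 18 of 28 genes lower when adjusted over the list alone. Its median was -0.45 without MDP CD103 low replicate 1. NF-kB targets (-0.46, adjusted p = 1.09e-09, but adjusted p = 0.202 with an estimated correlation), the GM-CSF list (-0.22, adjusted p = 0.00191, but adjusted p = 0.261 with an estimated correlation), interferon-stimulated genes (-0.21, adjusted p = 0.00952, but adjusted p = 0.585 with an estimated correlation), the NOD2 pathway (-0.13, adjusted p = 0.0235, but adjusted p = 0.287 with an estimated correlation) and glycolysis (0.10, adjusted p = 0.00875, but adjusted p = 0.278 with an estimated correlation) also differed as sets. With 1 array left out these medians came down to -0.32, -0.15, -0.07, -0.07 and 0.05. The responses of Itgae, 4.62-fold and 2.29-fold, were not shown to differ (-1.01 ± 0.34, adjusted p = 0.332). The count of 16 was 41 with same-numbered arrays as a block and 0 with Xist state as a covariate. It was 2, 10 and 0 without MDP CD103 low replicates 1, 2 and 3. It was 0 without PBS CD103 low replicate 1, 3 or 4, 41 without replicate 6, 0 without any 1 of the 3 MDP CD103 high replicates, and 107, 0 and 0 without PBS CD103 high replicates 4, 5 and 6.

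Averaged over treatments, 28 genes parted the subsets, 20 higher and 8 lower in CD103 high cells. Itgae was higher by 1.72 ± 0.17 (SE, 6 arrays against 7, adjusted p = 0.00399), and Ddx43, an RNA helicase, by 0.81 ± 0.09 (adjusted p = 0.00648). Emb was lower by -1.01 ± 0.11 (adjusted p = 0.00551), Cdk6 by -0.60 ± 0.09 (adjusted p = 0.0403), the inhibitory receptor Cd22 by -0.56 ± 0.09 (adjusted p = 0.0485), and Klrk1, which encodes NKG2D, by -0.36 ± 0.05 (adjusted p = 0.0387). Fcrla (0.52 ± 0.07, adjusted p = 0.0154), Plpp3, E2f7, Esyt3, Plb1 and Crim1 were also higher, by 0.48 to 0.69, and Bcl2, Ybx3 and Vcl lower. Chst9 and Hcar1, which were higher, and Bex6, which was lower, had means inside the olfactory receptor range. With the mean of its probe sets Emb differed by -0.49 and stayed past the threshold, while Bcl2 went from -0.40 to -0.21 and lost it (adjusted p = 0.0839). Of 18 named genes, only Itgae, Ddx43 and Emb kept their call in every alternative, and Vcl lost it in 17 of 24. The count of 28 was 64 with same-numbered arrays as a block and 0 with a fixed block on the 4 pairs, and centring each array by its median turned the split into 29 higher and 6 lower. Without MDP CD103 low replicates 1 and 3 it was 17 and 10, without PBS CD103 low replicates 1, 3, 4 and 6 it was 10, 4, 7 and 7. Without MDP CD103 high replicates 2, 3 and 4 it was 5, 3 and 3, and without PBS CD103 high replicates 4, 5 and 6 it was 10, 3 and 11.

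Averaged over subsets, 41 genes passed between MDP and PBS mice, 33 higher and 8 lower after MDP. Itgae rose by 1.70 ± 0.17 (SE, 6 arrays against 7, adjusted p = 0.00153) and Emb by 1.10 ± 0.11 (adjusted p = 0.00153). The TNF receptor family member Relt (0.78 ± 0.11, adjusted p = 0.0205), Lrr1 (0.77 ± 0.11, adjusted p = 0.0205), Cbx5, a heterochromatin protein (0.65 ± 0.09, adjusted p = 0.0167), and galectin-1, Lgals1 (0.62 ± 0.09, adjusted p = 0.0205), rose. So did Plet1, Cdk6 and BC055324, with adjusted p from 0.0338 to 0.0366, and Bex6 (0.79 ± 0.08, adjusted p = 0.00153), whose mean lay inside the olfactory receptor range. Ifitm6, of the interferon-induced transmembrane family, fell by 0.63 ± 0.08 (adjusted p = 0.0167) and Fcrla by 0.50 ± 0.07 (adjusted p = 0.0167). Cd300c, Afmid, Dkk3, Maml2, Zswim4 and Chst9 also fell. Of 18 named genes, only Itgae, Emb and Bex6 kept their call in every alternative, and Zswim4 lost it in 16 of 24. With the mean of its probe sets Emb rose by 0.54. With same-numbered arrays as a block the count was 13. The adjusted p was then 0.0561 for Plet1, BC055324, Cdk6, Chst9, Cd300c and Maml2, 0.076 for Afmid, 0.0604 for Dkk3 and 0.0827 for Zswim4. The count was 114, 15 and 14 without MDP CD103 low replicates 1, 2 and 3, and 22, 17 and 13 without PBS CD103 low replicates 1, 4 and 6. It was 4, 4 and 14 without MDP CD103 high replicates 2, 3 and 4, and 120, 3 and 4 without PBS CD103 high replicates 4, 5 and 6.

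Across all 7 contrasts, no change in Cd8a, Ly75, Nod2, Csf2ra, Csf2rb or Csf2rb2 passed the threshold. Nod2, the receptor for MDP, changed by 0.16 ± 0.10 in CD103 low cells (adjusted p = 0.831) and by -0.01 ± 0.11 in CD103 high cells (adjusted p = 0.986). Csf2ra, which encodes the alpha chain of the GM-CSF receptor, differed by 0.26 ± 0.09 between the subsets of PBS mice (adjusted p = 0.437) and changed by -0.29 ± 0.10 with MDP in CD103 high cells (adjusted p = 0.178). Csf2rb and Csf2rb2, which encode near-identical beta chains whose probes may not tell them apart, changed by 0.25 ± 0.12 (adjusted p = 0.814) and 0.31 ± 0.10 (adjusted p = 0.741) with MDP in CD103 low cells.

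Across genes, which are not independent replicates, the difference between the subsets in PBS mice had a Pearson r of -0.01 and a Spearman rho of -0.02 with that in MDP mice. The responses of the subsets to MDP had an r of 0.02 and a rho of 0.06 with each other. Genes higher in CD103 high than low cells after MDP were largely those that rose with MDP in CD103 high cells, with 88 genes in both groups where 1.49 would be shared if the calls were independent. The 7 genes lower in both, where 0.04 would be, include Ccl5 and Ccr7. These contrasts share the MDP CD103 high arrays, and their r of 0.56 compares with 0.50 when no gene is changed in simulated data, although the covariance of 0.0219 exceeds the simulated 0.0103. Of the genes that parted the subsets in PBS mice, 7 were higher in CD103 high cells and then fell there with MDP, where 0.04 would if the calls were independent. Among them were Pacsin1, Cd300c and Fcrla. A further 6 were lower and then rose, where 0.10 would, Emb among them. The latter contrasts share the PBS CD103 high arrays with opposite sign, and their r of -0.60 compares with -0.53 in simulated data with no gene changed (covariance -0.0182 against -0.0103).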

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

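The tests of sex as a cause, of RNA from another dividing cell type, of mixed RNA, of female mice and of splits that keep pairs were chosen only after the result was seen. The tests of mature cells, of the sort gate and of other splits were not.

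The difference between MDP and PBS was larger in the CD103 high than in the CD103 low gate for 16 genes. Among them, the log2 responses differed by 1.429 for Esco2, 1.388 for Ndc80, 1.364 for Atad2, 1.27 for Kif4 and 1.206 for Blm. They differed by 1.122 for Ncapg2, 1.121 for Fancd2, 1.053 for Rad54l, 1.044 for Mms22l and 1.029 for Cdc7. Each had an adjusted p of 0.0486 in limma. Only the real one of 100 splits (1) reached 16, and the highest of the others gave 6. With same-numbered arrays of a treatment kept together, 1 of 52 splits reached it and the highest other gave 0. Such splits exchange MDP and PBS arrays within each subset, so they stand for no response in either subset. They do not stand for an equal response in both, so chance is not excluded for a difference between the responses. For MDP against PBS in CD103 high cells, 1 of 10 splits reached the 403 genes of the real one and the highest other gave 0, and 10 splits are too few for a share under 0.05. The count of 16 was 0 with Xist state as a covariate, 41 with the replicate block and 23 with both. With the covariate the differences stayed at 0.966 to 1 of those without it (1.43 ± 0.19 and 1.42 ± 0.20 for Esco2, SE), and the calls ended because the adjusted p went from 0.0486 to between 0.0576 and 0.072, with a median SE of 0.167 before and 0.171 after, so that the loss is no evidence for sex as the cause. It was 2, 10 and 0 without MDP CD103 low replicates 1, 2 and 3, and 0, 0, 0 and 41 without PBS CD103 low replicates 1, 3, 4 and 6. It was 0 without MDP CD103 high replicate 2, 3 or 4, and 107, 0 and 0 without PBS CD103 high replicates 4, 5 and 6.

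An equal share of Xist-high arrays, 2 of 3 in MDP and in PBS (difference 0), argues against sex as an additive cause of the rise of cell cycle genes in CD103 high cells after MDP, while a response that depends on sex was not tested. RNA of another dividing cell type with few of its markers here is argued against, since the highest upper 95% bound of the 9 marker lists was 0.114, for natural killer cells, below 0.336, which is 50% of the cell cycle list's mean. That holds for granulocyte (2 of 14 markers above the olfactory receptor range), erythroid (0 of 6), B (2 of 11), T (3 of 11), natural killer (3 of 10) and B16 melanoma cells (3 of 10), but not for plasmacytoid cells (8 of 13), cDC2 (10 of 13) or monocytes (12 of 18), whose high baseline could hide a small share, although the sort on CD205 and CD8 selects against the latter 2 types. A lower share of CCR7-positive mature cells stays open, because with the mature list's mean as a covariate the median went from 0.72 to 0.48 (ratio 0.665) and the members past the threshold from 20 to 0, while their median SE went from 0.157 to 0.173. Entry into the cycle after MDP, or a dividing precursor sorted with these cells, may also account for it and was not tested, and only 3 members passed without MDP CD103 high replicate 2 or 3, 1 without PBS CD103 high replicate 5 and 0 without replicate 6.

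Itgae rose with MDP in both subsets, and a sort gate set higher in MDP mice could give this without a response of any cell. Such a shift should carry along other genes that part the subsets, which were chosen on some PBS arrays and measured on the rest in 18 splits (50 genes per direction of 11700, held-out difference 0.201, from 0.0368 to 0.339). They moved by -0.0989, a share of -0.493 of that difference (from -6.8 to -0.0519), in CD103 low cells. In CD103 high cells they moved by -0.271, a share of -1.35 (from -6.45 to -0.632). Both shifts were opposite to Itgae. The test assumes that MDP acts on these genes only through the gate. Yet 7 genes higher in CD103 high cells of PBS mice fell there with MDP, 6 lower ones rose, and 1, Itgae, was higher and rose. A response of such genes could hide a gate shift, so the test cannot decide. Sex is argued against in CD103 low cells, where the change of Itgae with Xist state as a covariate was 0.993 of that without it. A shifted gate and a rise of Itgae RNA in the cells after MDP both remain as hypotheses, and transcription itself was not measured. Nor was it tested whether cells passed from one gate to the other after MDP. The adjusted p of Itgae ranged from 0.00474 to 0.331 over the alternatives in CD103 low cells (0.331 with only the arrays compared, 0.0787 without MDP CD103 low replicate 2). In CD103 high cells it ranged from 0.00858 to 0.124 (0.124 without PBS CD103 high replicate 6).

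All mice are labelled male, yet 7 of 13 arrays had high Xist and Y-linked transcripts in the olfactory receptor range: PBS CD103 low replicates 1 and 4, PBS CD103 high replicates 4 and 5, MDP CD103 low replicate 3 and MDP CD103 high replicates 3 and 4. Female RNA mixed into male samples is argued against as their source, since 0 of the Xist-high arrays had Y-linked transcripts above that range, although 5 Xist-low arrays had Xist from 5.57 to 6.69, also above it, so that traces in those are not excluded. Female mice among those labelled male are consistent with the levels of Kdm6a and Kdm5c, which escape X inactivation and were higher in Xist-high arrays, at 9.88 ± 0.11 against 9.32 ± 0.11 and 8.87 ± 0.08 against 8.54 ± 0.10 (SD, n = 7 and 6 arrays), with an exact two-sided permutation p = 0.00794 each, also when adjusted over the 2 tests, with same-numbered arrays of a treatment averaged to 9 units (5 and 4). Xist-high arrays made up 2 of 4 in PBS CD103 low, 2 of 3 in PBS CD103 high, 1 of 3 in MDP CD103 low and 2 of 3 in MDP CD103 high cells.

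Of 216 named genes tested in the 4 PBS CD103 low arrays, 16 had an array far from the others in a Dixon test, which chance gives in about 1 in 20 groups. Replicate 1 was apart for Chst9 at 2.762, Slc4a1 at 5.128, Mitf at 6.642, Rhag at 3.794, Itgb8 at 4.655 and Ncapg2 at 7.823. Replicate 3 was apart for Ybx3 at 10.27. Replicate 4 was apart for Ttc39b at 7.285, S100a8 at 2.285 and Ccl17 at 3.802. Replicate 6 was apart for Fcrla at 8.184, Tlr12 at 8.156, Stil at 7.411, Oas2 at 4.963, Cdkn1a at 7.879 and Lrrc32 at 5.545.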

How the results depend on the processing

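The Xist covariate and the list tests with the replicate block were chosen only after the result was seen, unlike the other alternatives. Of 2980 recomputed values of 117 gene results, 2067 kept their direction and side of the threshold, 903 lost their call, 10 gained one and 0 reversed. Unlike the counts per gene above, these include the 2-fold minimum, under which every call with a smaller change is lost by definition. Counts of genes past the threshold were less stable. The contrasts between subsets in PBS mice and in MDP mice had 17 and 116 genes, and those between treatments in CD103 low and CD103 high cells 1 and 403. The average over treatments had 28, the average over subsets 41 and the interaction 16. In this order, leaving out 1 array gave 2 to 23, 0 to 140, 0 to 2, 82 to 594, 3 to 23, 3 to 120 and 0 to 107. Fitting only the arrays compared gave 1, 0, 0 and 200 for the contrasts within a treatment or subset. Fewer arrays then estimate the spread, and it is no longer shared with the other groups. Groups differed in spread for some genes, as for Ccr7 with an SD of 0.97 in MDP and 0.06 in PBS CD103 low cells. A shared spread can make the SE too small for the more variable group. Which of these lowered the counts was not tested. Requiring a 2-fold change gave 3, 13, 32, 2, 2 and 10 for all contrasts but CD103 low cells, which kept 1. Leaving out the lowest 25% of genes gave 62, 116 and 38 for the averages and the interaction. Leaving out the lowest 50% gave 233 in MDP mice, 702 in CD103 high cells, and 85, 231 and 144, since fewer genes are tested. A variance trend with robust fit gave 192 in MDP mice, 0 in CD103 low cells, 609 in CD103 high cells, and 87, 187 and 116. Array weights gave 49, 97 and 35 for the last 3, and renewed quantile normalisation gave 29 for the interaction. The cause was not tested. The replicate block of treatment and number gave 190 in MDP mice, 2 in CD103 low cells, 64 and 13 for the averages and 41 for the interaction, and left the counts of PBS mice and CD103 high cells within 1.5 times. A block by number alone gave 2 in CD103 low cells, 46 for the average over treatments and 27 for the interaction, and a fixed block on the 4 pairs, with 8 arrays and 3 residual degrees of freedom, gave 0 for the average over treatments. Xist state as a covariate gave 61 in MDP mice, 14 for the average over treatments and 0 for the interaction, and with the block it gave 26 for the average over subsets, for causes not tested.

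Of the 49 list tests past the threshold, 0 passed with an estimated correlation and fry passed 6. With the replicate block the numbers were 49, 0 and 6. The block brought pattern-recognition receptors in CD103 high cells to an adjusted p = 0.0479 and took immediate-early genes in the average over subsets to an adjusted p = 0.106 in camera. In fry it brought migration genes in MDP mice to an adjusted p = 0.0336 and took glycolysis in the average over subsets to an adjusted p = 0.0654. Among named genes the block changed the calls given beside them for Itgae in MDP mice and for 9 genes in the average over subsets, and changed no other. Signal over background limits Chst9, Hcar1, Bex6 and Scarna10, whose means lie inside the olfactory receptor range.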

Other observations

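The tests of whether the subset profile is kept after MDP and of splits that treat same-numbered arrays of a treatment as pairs were chosen only after the result was seen. The tests of all splits and of opposite movement were not.

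Averaged over subsets, MDP was followed by a higher glycolysis list, with a median of 0.10 (adjusted p = 0.000166, but adjusted p = 0.395 with an estimated correlation, adjusted p = 0.046 in fry and 0.0654 in fry with the replicate block). No member passed over all genes and 3 rose when adjusted over the list alone, with Pkm at 0.21 (adjusted p = 0.0698) and Tpi1 at 0.22 (adjusted p = 0.119) foremost. The interferon-stimulated list was lower, with a median of -0.18 (adjusted p = 0.000166, but adjusted p = 0.621 with an estimated correlation), and Ifit1 at -0.25 (adjusted p = 0.127) and Ifit3 at -0.20 (adjusted p = 0.324) had the smallest p. Averaged over treatments, cholesterol synthesis genes were lower in CD103 high cells, with a median of -0.13 (adjusted p = 2.19e-05, but adjusted p = 0.528 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, differed by -0.43 (adjusted p = 0.0987) and Mvd by -0.31 (adjusted p = 0.103), and 4 of 14 were lower when adjusted over the list alone. Tlr2 differed by -0.27 (adjusted p = 0.0987) and the chemokine receptor Ccr2 by -0.85 (adjusted p = 0.124), neither past the threshold.

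MDP CD103 low replicate 1 lay at -29.5 on the principal component with the most variance (18.8%), where the MDP CD103 high arrays lay at 11.6 to 17.4, and its array weight of 0.548 was the lowest of 13. Its mean of the mature list was 8.50, against 7.45 and 7.47 in the other arrays of its group.

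Other splits of the arrays bear on whether the counts arise by chance. Between the subsets of PBS mice, 1 of 35 splits, the real one with 17 genes, reached that count. The highest of the others gave 12. Those that part as many pairs as the real one gave at most 0, and with it they are 12, too few for a share under 0.05. In CD103 low cells 1 of 35 reached the real count of 1, with 0 in the highest other, the smallest share that 35 splits can give. The count is 1 gene, Itgae, whose call was lost in 4 of 25 alternatives, so chance is not excluded. For the average over treatments 1 of 100 reached 28, with 1 in the highest other. Of all 96 splits that part as many pairs, 2 did, a share of 0.0208. The other one gave 31 genes, more than the real one, and exchanges the subsets in all MDP arrays and in PBS replicate 4. It thus holds the real difference of MDP mice with its sign turned. Such a split does not stand for no difference, so it does not show that chance reaches the count. The fixed block on the 4 pairs gave 0 genes, but with 8 arrays and 3 residual degrees of freedom it may miss real differences. Chance is not taken as excluded for this count. Between the subsets of MDP mice, with 116 genes in the real split and 0 in the highest other, 1 of the 10 splits reached it, as did 1 of the 4 that part as many pairs, with 0 in the highest other. Neither number allows a share under 0.05. For the average over subsets 3 of 100 reached 41, but 6 of the 52 splits that keep each pair in 1 treatment did (a share of 0.115), with 413 genes in the highest other. The split with 413 exchanges all CD103 high arrays between the treatments, so it holds the real difference of those cells with its sign turned. Such a split does not stand for no response, so the share cannot decide. Chance is not excluded for the count of 41, which was 13 with the replicate block. The highest of the 100, with 252 genes, swaps MDP CD103 low replicate 1 with PBS CD103 low replicate 1. It leaves the CD103 high arrays in their real groups, so it too keeps their difference. That the count rose with this swap points to a structure of the samples around MDP CD103 low replicate 1.

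A hypothesis is that cell cycle and CCR7-type mature genes trade off between cells, so that arrays with more of the mature transcripts hold fewer of the other. As deviations from the group means of 13 arrays, the list means had Pearson r = -0.708 (permutation p = 0.127, 1e+05 resamples) and Spearman rho = -0.604 (permutation p = 0.129), two-sided and the only relation of its kind tested, so that the adjusted values are the same. Without the 2 arrays farthest from the median, MDP CD103 low replicates 1 and 2, r was -0.386. The deviations behind that value were still taken from group means that include these 2 arrays, so it does not fully remove them. Without replicate 1 alone, and with its group mean taken anew, r was -0.24, so that the size of the relation rests on that array. The test was written to count a p of 0.05 or more as evidence against the trade-off. That was wrong, since missing the threshold with 13 arrays does not show that r is 0, and the hypothesis stays open.

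Another hypothesis is that the profile that parts CD103 high from low cells in PBS mice is kept after MDP, when both subsets have more Itgae. Of the 16 other genes past the threshold in PBS mice, 14 had the same sign in MDP mice and 0 passed there, with a median signed difference of 0.235 against 0.746, the latter raised by the choice of the genes. A profile chosen on part of the PBS arrays differed between the subsets of MDP mice by 0.178 of its held-out difference in PBS mice, from -2.31 to 2.15 over 18 splits, a spread too wide to decide. Whether the subsets after MDP may still differ as they did before thus cannot be told apart from a loss of the difference, with 3 or 4 arrays per group.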
